A study of Rattus norvegicus with 6 samples.

How the data were processed

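RNA abundance was measured in 6 libraries of HEI-OC1 cells, 3 treated with an siRNA against Hnrnpd and 3 with a control siRNA. Per the labels' protocols, the cells grew at 37 °C with 5% CO2 in medium with 10% serum, RNA was isolated with TRIzol and treated with DNase, and the libraries were read as 150 nt paired ends on a NovaSeq 6000. The labels give the organism as rat. HEI-OC1 is generally known as a mouse line, and the species of the reads was not tested here, so levels compared between genes should be read with that limit.

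The reads were aligned by the authors with TopHat2, version not given in the sources used here, per the submitters' processing notes. Those notes name the build mRatBN7.2, while the contig names in the deposited tables belong to another rat assembly, so the build behind the gene models is uncertain and no coordinates are given. The read counter, its strand setting and the annotation version are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. The first deposited table holds whole-number read counts per gene, not normalized, for 18718 genes with at least 1 count. The libraries held 28984535 to 35842904 counts each. The second deposited table holds FPKM values computed by the authors for 18628 genes. Each column was matched to its sample by its siRNA name and replicate number, and 0 columns stayed without a sample. Gene names came from the tables. For the gene lists, 820 of 947 entries matched by symbol, 21 through synonyms in a RefSeq gene table of the rat assembly GRCr8, and 106 were unmatched.

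Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, a quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment over 12268 genes, with calls at an adjusted p under 0.05. CPM values use library sizes after TMM scaling. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01, and adjusted over the 31 lists with at least 5 tested members. The same lists were tested with an estimated correlation and with fry. The 34 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Hnrnpd, then up to 12 highest and 12 lowest log2 changes among called genes with a mean of at least 5 CPM, no overlap between groups and a gene symbol, then up to 4 members of each list with the smallest adjusted p. Most further list members named in the text were called over their list alone, and others are named with the reason. Enoph1, Cdkn1a, Cdkn2a, Vim, Il1rn, Dcn, Postn, Acta2 and Myo6 were named after their values were seen. Not every gene that these rules take is named in the text, and some results are not reported here.

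Alternatives were DESeq2 1.42.0, limma-voom, size factors (RLE) and upper-quartile scaling in edgeR, no filter, a filter of at least 50 counts in 3 libraries, the replicate number as a block, leaving out each library, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or without that minimum. A log2 change on the FPKM scale understates the change of low genes because of the pseudocount. All 15 pairs of libraries differed by more than sampling noise, so no library was counted as a duplicate.

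The tests were run on simulated counts with known changes, drawn from the means, library sizes and dispersions of the siHnrnpd and control libraries. For that comparison, with 12176 simulated genes in the step, edgeR recovered 66.7% of 48 genes changed 1.5-fold, 82.0% of 50 changed 2-fold, 100% of 50 changed 4-fold and 100% of 48 changed 8-fold, and 7.57% of its 185 calls were false. DESeq2, with 12267 simulated genes in its step, recovered 76.0% of 50 genes changed 1.5-fold, and 9.23% of its 195 calls were false. The simulated genes vary independently of each other, unlike real ones. The simulation also held many more changed genes than edgeR called in the real data, where it called 10. More changed genes make the adjusted threshold easier to pass, so the recovered shares are not the power of the real comparison. The median SE of a log2 change in the real data was 0.10, and the biological coefficient of variation was 10.3%.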

Results

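Total RNA was sequenced from HEI-OC1 cells, an established auditory cell line derived from the organ of Corti, after treatment with an siRNA against Hnrnpd or with a control siRNA. Hnrnpd encodes AUF1, an RNA-binding protein that attaches to AU-rich elements in mRNA and influences how fast those mRNAs decay. The series title names senescence, immune response genes and alternative splicing as its subjects. Each of the 2 groups held 3 libraries, called control 1 to 3 and siHnrnpd 1 to 3. The libraries held 28984535 to 35842904 gene counts, and 15583 to 15926 genes had at least 1 count in a library. After a filter on low counts, 12268 genes were tested. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

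The siRNA target was measured first. Hnrnpd (listed as Hnrpd, ENSRNOG00000002292, chromosome 14) had 297 ± 25.9 CPM in the control libraries and 187 ± 12.2 CPM in the siHnrnpd libraries (SD, n = 3 each), which is 62.8% of the control mean. The counts behind these values were 9267, 9445 and 9709 in controls 1 to 3 and 6183, 6633 and 5976 in siHnrnpd 1 to 3. By the authors' FPKM the level was 149 ± 11.5 in control and 94.5 ± 5.45 in siHnrnpd (SD, n = 3 each), or 63.6% of control. All 3 siHnrnpd libraries lay below all 3 control libraries, and the log2 change was -0.67 with an SE of 0.082 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0426). Without siHnrnpd 2 the adjusted p was 0.0458. Leaving out any other library gave an adjusted p of 0.0508 to 0.319, with a log2 change of -0.74 to -0.63 over the 6 fits.

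The comparison of the groups asks which transcripts change level when Hnrnpd is reduced. Among the genes that fell were Gbp2 and Gbp5, guanylate-binding proteins induced by interferon, with log2 changes of -1.19 and -0.94. Haptoglobin (Hp), an acute phase protein that binds haemoglobin, fell by 0.81 on the log2 scale, and complement component C6, part of the membrane attack complex, fell by 0.86. Lgmn, the lysosomal protease legumain, rose from 116 ± 4.34 to 173 ± 13.1 CPM (SD, n = 3 each). The phosphate transporter Slc20a2 rose from 39.1 ± 1.64 to 57.5 ± 2.19 CPM, and Syde1 rose from 21.3 ± 1.51 to 34.3 ± 2.88 CPM (SD, n = 3 each). In each of these genes the 3 libraries of a group lay apart from the 3 of the other group.

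Gbp2 had 61.1 ± 3.01 CPM in control and 26.8 ± 5.18 CPM in siHnrnpd (SD, n = 3 each). Gbp5 had 42.2 ± 2.80 and 22.0 ± 4.23 CPM, Hp 96.4 ± 5.07 and 54.9 ± 7.45 CPM, and C6 13.4 ± 1.58 and 7.35 ± 0.25 CPM. The guanylate-binding proteins form a family of similar genes, so reads may have been split between copies. The row listed as Tas1r2, named for a sweet taste receptor subunit, fell from 127 ± 5.61 to 89.1 ± 4.53 CPM. Its identity is uncertain, since the gene name table used here gives Aldh4a1, the neighbouring gene, also as a synonym of Tas1r2, and the count table has no row named Aldh4a1. Cst7, the protease inhibitor cystatin F, fell from 6.88 ± 0.61 to 1.86 ± 0.77 CPM, a log2 change of -1.88. It lies under the CPM minimum for named genes and is given because its values were seen.

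In all, edgeR's quasi-likelihood test called 10 of 12268 genes at an adjusted p under 0.05, 3 higher and 7 lower with the siRNA, with adjusted p from 0.0426 to 0.0473. Of these, 2 (Cst7 and Gbp2) changed at least 2-fold. At an FDR of 0.1 the count was 36, of which 11 were higher and 25 lower. At an unadjusted p under 0.05, 717 genes were higher and 638 lower, against 613.4 genes expected in total if no gene changed. Genes are not independent, so such a count can vary widely around that value. Another split of the 6 libraries gave 2309 genes in total. The groups did not overlap in 2084 genes, or 17.0%, against 10% by chance. DESeq2 called 162 genes, 55 higher and 107 lower, and all 10 of the edgeR calls were among them. By edgeR 0 genes were called without control 1, without control 2 or without control 3, with 964, 724 and 1919 genes at an unadjusted p under 0.05, while 1, 7 and 14 genes were called without siHnrnpd 1, 2 and 3.

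**Figure D1:**
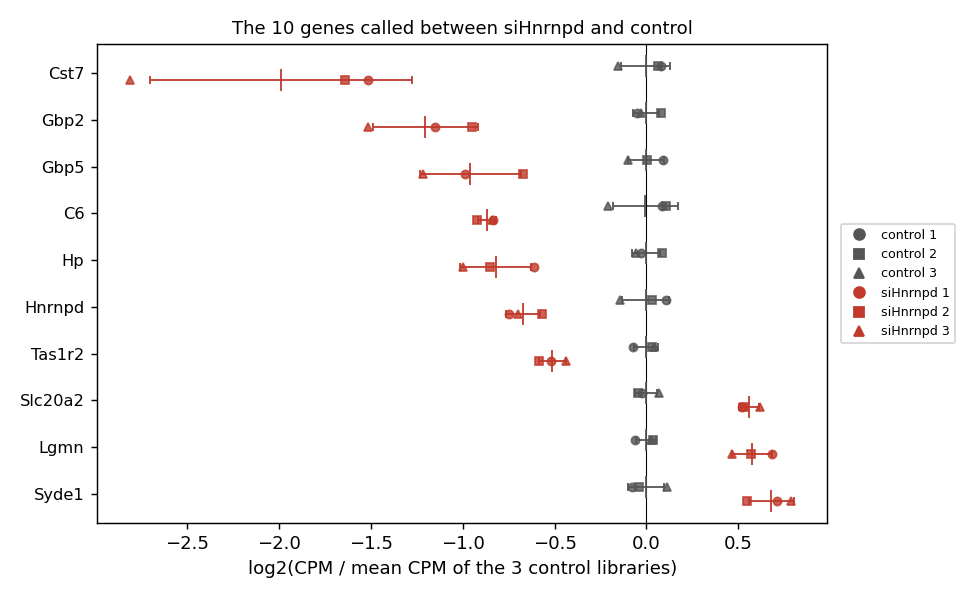
Level of each of the 10 called genes in each library, as log2 of its CPM over the mean CPM of the 3 control libraries, with control in grey and siHnrnpd in red. Points are libraries, the upright tick is the group mean and the bar is 1 SD (n = 3). Hnrnpd sits between -0.75 and -0.57 in the siHnrnpd libraries, and Cst7 reaches -2.81 in siHnrnpd 3.

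Immune genes were examined because the series title names them. Interferon-stimulated genes were lower in the siHnrnpd libraries: all 51 tested members had a negative log2 change, with a median of -0.72. Gbp2 and Gbp5 were called over all genes tested, 26 members were called lower when adjusted over the list alone, and 34 did not overlap between the groups. DESeq2 called 9 lower. Cxcl10, an interferon-induced chemokine, had 2867 ± 389 CPM in control and 1391 ± 310 CPM in siHnrnpd (SD, n = 3 each), and its log2 value of -1.04 did not pass over all genes (edgeR adjusted p = 0.0615). Cxcl11, a chemokine that shares its receptor, had a log2 value of -1.69 (edgeR adjusted p = 0.0615). The list passed camera with a preset correlation (adjusted p = 8.74e-20) and did not with an estimated one (adjusted p = 0.826 with an estimated correlation). The correlation estimated between its members was 0.89 against the preset 0.01, so the preset p-value is far too small if that estimate holds. Relative to the control mean, the mean log2 CPM of the list was -0.48 in siHnrnpd 1, -0.39 in siHnrnpd 2 and -1.87 in siHnrnpd 3, and -0.13, 0.19 and -0.063 in controls 1 to 3. Without siHnrnpd 3 the list's median was -0.40. That library also stood apart in fibroblast and mesenchymal markers, at 0.27 above the control mean against 0.052 and 0.030 in siHnrnpd 1 and 2, and in supporting cell and prosensory markers, at 0.28 against -0.0090 and 0.022. Neither list passed (camera preset adjusted p = 0.0706 and 0.186).

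Genes of MHC class I antigen presentation, which load peptides onto the cell surface, were also lower as a list. Of 22 tested members, 21 had a negative log2 change, the median was -0.31, and 0 were called by edgeR, over all genes or over the list alone (camera preset adjusted p = 1.00e-05; adjusted p = 0.826 with an estimated correlation). At an unadjusted p under 0.05, 8 were lower. DESeq2 called 2 lower, and 8 members did not overlap between the groups. B2m, the light chain of the class I complex, had a log2 value of -0.32 and the immunoproteasome subunit Psmb9 one of -0.58, with edgeR adjusted p of 0.341 and 0.322. The list mean was -0.86 in siHnrnpd 3, against -0.17 and -0.12 in siHnrnpd 1 and 2 and -0.14, 0.11 and 0.031 in controls 1 to 3, so the list means of the groups overlapped. The median without siHnrnpd 3 was -0.18. The class I heavy chain genes of the rat are near copies of each other, so their counts are uncertain.

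Complement and acute phase genes gave a median of -0.20 over 17 tested members, 14 of them negative (camera preset adjusted p = 4.53e-05; adjusted p = 0.826 with an estimated correlation). Hp was the member called over all genes, and 4 were called lower when adjusted over the list alone: Hp, Orm1, C1s and C1r. Orm1, an acute phase glycoprotein, had a log2 value of -0.64, and the complement proteases C1s and C1r had -0.49 and -0.43. The list mean was -0.16, -0.18 and -0.64 in siHnrnpd 1, 2 and 3, and the median without siHnrnpd 2 was -0.30. C6 was not on this list. For targets and regulators of NF-kB the median was -0.020 over 28 tested members, with 4 called lower over the list alone and a camera preset adjusted p of 0.0854. That median was -0.093 without siHnrnpd 1 and -0.0071 without control 2, and the list mean was -0.37 in siHnrnpd 3 against -0.044 and 0.0046 in siHnrnpd 1 and 2 and -0.060 in control 1. The 4 called lower were the chemokines Ccl2, Cxcl1 and Cxcl3 and the adhesion molecule Vcam1.

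Senescence was addressed through secreted factors, p53 targets and cell cycle genes. Senescence-associated secreted factors were lower as a list, with a median of -0.21 over 28 tested members (camera preset adjusted p = 0.00184; adjusted p = 0.826 with an estimated correlation). By edgeR 0 members were called over all genes, with 3 higher and 8 lower at an unadjusted p under 0.05, while DESeq2 called 1 higher and 5 lower. Over the list alone, 1 was called higher and 6 lower (Cxcl12, Ccl2, Csf1, Ccl7, Cxcl1 and Cxcl3). Of these, Ccl2, Cxcl1 and Cxcl3 are also on the NF-kB list, so the results of these lists are not independent. Cxcl12 had a log2 value of -0.49 and Csf1, the macrophage growth factor, one of -0.44. The list mean was -0.49 in siHnrnpd 3 and -0.055 and -0.047 in siHnrnpd 1 and 2, while control 1 lay at -0.061, so the list means of the groups overlapped. The median was -0.12 with DESeq2 and -0.098 on log2(FPKM + 1), over 39 and 23 members. Without siHnrnpd 3 the median was -0.094 and the call was lost (camera preset adjusted p = 0.0661).

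The p53 targets and cell cycle arrest genes had a median of 0.044 over 23 tested members and did not pass (camera preset adjusted p = 0.227), although without siHnrnpd 3 they did (adjusted p = 0.0169). That median was 0.11 without siHnrnpd 3, 0.081 without control 3 and 0.030 without siHnrnpd 1. With an estimated correlation and all 6 libraries the adjusted p was 0.826. Over the list alone, the p53-responsive kinase genes Plk3 (log2 value 0.43) and Plk2 (-0.46) were called in opposite directions. The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2a, both widely used senescence markers, had log2 values of 0.022 and 0.044. Glb1, which encodes the lysosomal beta-galactosidase stained in senescence assays, had 92.6 ± 3.55 CPM in control and 68.9 ± 1.65 CPM in siHnrnpd (SD, n = 3 each), and its log2 value of -0.43 did not pass over all genes (edgeR adjusted p = 0.0613). Mitotic genes had a median of -0.0043 over 28 tested members (camera preset adjusted p = 0.831). Their median was -0.062 without siHnrnpd 3, with 22 members lower, and 0.013 without control 1. Leaving out 1 library gave camera preset adjusted p of 0.265 to 0.986. DNA replication genes were lower as a list, with a median of -0.034 over 34 tested members, with 0 members called by edgeR or DESeq2 and 3 lower at an unadjusted p under 0.05 (camera preset adjusted p = 0.0270; adjusted p = 0.826 with an estimated correlation). The median was -0.079 without control 3, -0.076 without siHnrnpd 3 and -0.054 without control 1, but -0.022 with upper-quartile scaling and -0.016 on log2(FPKM + 1). The call was lost without control 2 (adjusted p = 0.0988) and without siHnrnpd 2 (adjusted p = 0.250).

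Known AUF1 target mRNAs, collected from earlier literature, did not pass as a list: the median was -0.012 over 24 tested members, 11 positive and 13 negative (camera preset adjusted p = 0.958). Camera looks for a shared direction, so it cannot detect targets that moved in opposite directions. The fry test for change in either direction did not pass (adjusted p = 0.353). Of 32 listed targets, 27 matched, while Tnf, Il1b, Il10, Nos2 and Adrb1 did not. Mmp9, Csf2 and Pth were under the filter. Ccl2, a monocyte chemokine, was the member called over the list alone, with 356 ± 32.0 CPM in control and 214 ± 40.04 CPM in siHnrnpd (SD, n = 3 each). The same gene is also on the NF-kB and secreted factor lists. The log2 value of Ccl2, -0.74, did not pass over all genes (edgeR adjusted p = 0.0804). Ccnd1, the cyclin of the G1 phase, had a log2 value of 0.35 (edgeR adjusted p = 0.310). Among 18 tested proteins that bind AU-rich elements, the median was 0.014 (camera preset adjusted p = 0.913). Over the list alone, Hnrnpdl, a close paralog of Hnrnpd, was called higher and Hnrnpab lower. Hnrnpdl had 115 ± 8.08 CPM in control and 166 ± 9.55 CPM in siHnrnpd (SD, n = 3 each), a log2 value of 0.53 that did not pass over all genes (edgeR adjusted p = 0.0560). Because Hnrnpd, Hnrnpdl and Hnrnpab are similar in sequence, reads may have been split among them.

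Splicing itself was not analysed here, since the tables hold 1 value per gene. The levels of SR proteins and other splicing regulators had a median of -0.013 over 36 tested members (camera preset adjusted p = 0.831). Rbm3, a cold-inducible RNA-binding protein, was the member called over the list alone, with a log2 value of 0.39 (edgeR adjusted p over all genes = 0.0676).

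Genes of glycolysis and hypoxia were higher as a list, with 21 of 27 tested members positive and a median of 0.24 (camera preset adjusted p = 4.61e-04; adjusted p = 0.881 with an estimated correlation). By edgeR 0 members were called, over all genes or over the list alone, with 13 higher at an unadjusted p under 0.05, while DESeq2 called 4 higher. Car9, a hypoxia-induced carbonic anhydrase, had a log2 value of 0.75, the glucose transporter Slc2a1 one of 0.49 and the enolase Eno1 one of 0.39, with edgeR adjusted p of 0.203, 0.295 and 0.261. The list mean was 0.36 and 0.27 above the control mean in siHnrnpd 1 and 2 and -0.026 from it in siHnrnpd 3, within the controls' -0.068 to 0.052, and the median without siHnrnpd 1 was 0.16. Cholesterol synthesis genes had a median of 0.15 over 22 tested members, 18 of them positive (camera preset adjusted p = 0.00119; adjusted p = 0.826 with an estimated correlation). Over the list alone, Fdft1, which encodes squalene synthase, and the sterol carrier Stard4 were called higher, with log2 values of 0.38 and 0.40. The list mean was 0.17 and 0.18 above the control mean in siHnrnpd 1 and 2 and 0.029 above it in siHnrnpd 3, and the median without siHnrnpd 2 was 0.094.

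**Figure D2:**
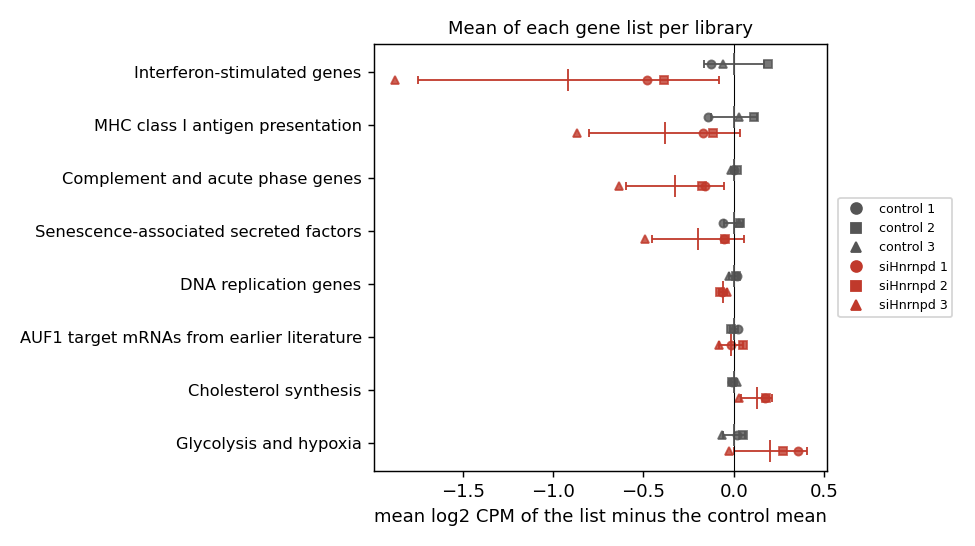
Mean log2 CPM of the tested members of 8 gene lists in each library, minus the mean of the 3 control libraries, with control in grey and siHnrnpd in red. Points are libraries, the upright tick is the group mean and the bar is 1 SD (n = 3). The interferon-stimulated genes sit at -1.87 in siHnrnpd 3 and at -0.48 and -0.39 in siHnrnpd 1 and 2.

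Over all 31 lists tested, camera with the preset correlation called 7, and camera with an estimated correlation called 0, with a lowest adjusted p of 0.826 and 0 lists at an unadjusted p under 0.05. The directional fry test also called 0 lists (lowest adjusted p = 0.291, with 5 lists at an unadjusted p under 0.05), and the fry test for change in either direction called 8. The 24 lists that camera did not call had medians between -0.10 and 0.13 and adjusted p from 0.0706 to 0.958. Among the 7 called lists the estimated correlation ran from 0.056 in DNA replication genes to 0.89 in interferon-stimulated genes, against the preset 0.01. A preset under the real correlation gives p-values that are too small. For the mean of 1 list per library, an exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1. Among the called lists that test gave 0.1 for interferon-stimulated, complement and acute phase, DNA replication and cholesterol synthesis genes. It gave 0.2 for MHC class I antigen presentation and 0.3 for senescence-associated secreted factors and for glycolysis and hypoxia. Uncalled lists also reached 0.1: p53 targets, DNA and RNA sensing, and telomere maintenance.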

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

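The alternatives were fixed before the data were examined. The 10 called genes had the same sign under all 16 alternatives, but the counts moved: from 10 called, 3 higher and 7 lower and 2 with at least a 2-fold change, to 162, 55, 107 and 8 with DESeq2 and to 147, 46, 101 and 27 with no filter on low counts, and both of these held all 10 genes. Limma-voom called 5 genes higher, and so did the filter of at least 50 counts in 3 libraries. Upper-quartile scaling in edgeR called 6 genes, all among the 10, 3 of them lower and 1 with at least a 2-fold change. Size factors (RLE) called the same 10 genes. On log2(FPKM + 1), limma called 0 genes, 0 higher, 0 lower and 0 with a 2-fold change, with or without the filter, where 1157 and 1604 genes had an unadjusted p under 0.05. On log2(FPKM + 0.1) it called 5 genes, 1 higher, 4 lower and 1 with at least a 2-fold change. The causes were not tested. Leaving out 1 library gave 0 to 14 called genes, 0 to 7 higher, 0 to 7 lower and 0 to 4 with at least a 2-fold change. Hnrnpd had a log2 change of -0.65 on log2(FPKM + 1), with and without the filter (adjusted p = 0.0508 and 0.137), and of -0.74 to -0.63 when 1 library was left out. Over all alternatives its adjusted p ran from 2.11e-10 to 0.319.

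With the replicate number as a block, edgeR called 0 genes, 0 higher, 0 lower and 0 with a 2-fold change, with 1062 genes at an unadjusted p under 0.05, and Hnrnpd had a log2 change of -0.67 (adjusted p = 0.0873). The labels do not pair the libraries. Same-numbered libraries correlated at -0.26, 0.14 and 0.10 in their deviations from the group means, within the -0.33 to 0.23 of differently numbered ones. With 3 libraries per group the deviations depend on each other, so these values cannot exclude a pairing. The block also moved the lists of DNA replication genes to an adjusted p of 0.0503 and of fibroblast and mesenchymal markers to 0.0440.

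With an estimated correlation all 7 list calls were lost, at an adjusted p of 0.826 for 6 lists and 0.881 for glycolysis and hypoxia. With fry they were lost at 0.291 for senescence-associated secreted factors, complement and acute phase genes, DNA replication genes and cholesterol synthesis, 0.451 for interferon-stimulated genes, and 0.491 for MHC class I antigen presentation and for glycolysis and hypoxia. Size factors (RLE) changed no list's call, nor did the 50-count filter in the 29 lists that kept enough members. When 1 library was left out, adjusted p ran from 4.11e-04 to 0.0661 for senescence-associated secreted factors, 0.00910 to 0.250 for DNA replication genes, 0.0169 to 0.545 for p53 targets, 0.0136 to 0.718 for NF-kB targets, 0.0136 to 0.718 for fibroblast and mesenchymal markers, 0.0226 to 0.397 for DNA and RNA sensing, 0.0226 to 0.896 for supporting cell markers, 0.0282 to 0.708 for lysosome and autophagy, 0.0160 to 0.937 for mitochondrially encoded genes, 7.60e-09 to 0.938 for the integrated stress and unfolded protein response, 0.00536 to 0.925 for ribosomal proteins and 0.00884 to 0.698 for DNA damage repair.

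Of 1956 values of 124 named genes other than Hnrnpd under the alternatives, 1819 kept their direction and their side of the threshold, 72 lost a call and 62 gained one, 51 of these with DESeq2 or no filter. Only genes called in the main fit could lose a call, and most of their values did. Each of these was called in 5 (C6) to 9 (Gbp2 and Hp) of 16 alternatives, and Hnrnpd in 8. The sign turned in 3 of the 1956 values, none of them called: Egr2 was at 0.13 without control 1 and at 0.037 without siHnrnpd 1, within a range of -0.23 to 0.13 over the left-out libraries, and Cnp was at 0.019 without siHnrnpd 3, within a range of -0.25 to 0.019. Many genes of few counts did not reach a test: the 18 matched hair cell markers had a median of 0.10 CPM, and 7 of them passed the filter. The cause of their low counts was not tested.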

Other observations

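All tests of explanations in this part were chosen after the results were seen. Marker lists gave a mixed picture of cell identity. Among fibroblast and mesenchymal genes, vimentin (Vim) averaged 4015 CPM and Col1a1 2347 CPM over the 6 libraries, while Dcn, Postn and Acta2 of the same list had at most 10 counts in a library and were under the filter. The median over its 22 matched members was 37.5 CPM. Of hair cell markers, 18 of 29 entries matched, with a median of 0.10 CPM, and 7 were tested, with a median of 0.67 CPM. Triobp (98.9 CPM) and Myo6 (35.5 CPM) lay far above both medians. The deposited counts cover only genes with at least 1 count, so an unmatched marker may be undetected or listed under another name. Unmatched hair cell markers included Atoh1, Pou4f3 and Tmc1. Medians over matched genes leave such markers out. Markers of neurons, leukocytes and epithelium had 2, 4 and 4 members that passed the filter, too few for a list test, and their matched genes had medians of 0.019, 0.13 and 0.046 CPM. The most abundant transcripts were mostly mitochondrial, with Mt-co1 at 1.73% of all counts, and included the interleukin-1 receptor antagonist Il1rn at 0.55%.

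Lysosome and autophagy genes passed the fry test for change in either direction (adjusted p = 1.95e-04), while their median was -0.037 and camera did not call them (preset adjusted p = 0.232). Adjusted over the list alone, Glb1 and the lysosomal membrane protein Lamp1 were called lower, with log2 values of -0.43 and -0.29. Immediate early genes passed the same fry test (adjusted p = 0.00377), and Ier5 was called lower (-0.32) and Maff and Klf4 higher (0.30 and 0.27) over the list alone. Among DNA repair genes, Xrcc6, which encodes the Ku70 subunit of the end-joining complex, and Fancd2 were called lower over the list alone, with log2 values of -0.30 and -0.26. None of these 7 genes passed over all genes in edgeR, and each had an unadjusted p under 0.05. Genes of the integrated stress and unfolded protein response had a list mean 0.28 and 0.19 above the control mean in siHnrnpd 1 and 2 and -0.20 from it in siHnrnpd 3. They passed camera without siHnrnpd 3 (preset adjusted p = 7.60e-09) and not with it (0.133). With an estimated correlation and all 6 libraries the adjusted p was 0.941.

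A first pattern is the lower level of interferon-stimulated genes, lowest in siHnrnpd 3, where fibroblast and supporting cell markers also lay 0.27 and 0.28 above the control mean. Scaling of the libraries is argued against, since the list's median lay -0.73 from the median of all tested genes. That siHnrnpd 3 alone carries the whole change is also argued against: without it the list mean of the siHnrnpd libraries was -0.43 from the control mean, with an SE over libraries of 0.13. With all 3 siHnrnpd libraries that difference was -0.91, so siHnrnpd 3 does carry a large part of the change. The value without it rests on siHnrnpd 1 and siHnrnpd 2 alone. An interferon state that differs between cultures whatever the siRNA stays open, because the 3 siHnrnpd libraries ranged over 1.49 on the log2 scale, more than the gap of 0.26 between the lowest control and the highest siHnrnpd library. Both groups received an siRNA, so a response to any siRNA would be shared. A response to the sequence of either siRNA is confounded with the groups, here and for the other genes and lists, and was not tested. A role of AUF1 in interferon signalling remains a hypothesis beside these.

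A second pattern is the higher level of glycolysis and hypoxia genes. A culture state, such as density or oxygen, that differs between libraries of one group may account for it: siHnrnpd 3 lay at -0.026 from the control mean, within the control SD of 0.061, while siHnrnpd 1 and 2 lay at 0.36 and 0.27. The real grouping gave an absolute median of 0.24, and another split of the libraries gave 0.25. An effect of the knockdown in 2 of 3 libraries was not tested apart from this.

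A further pattern sits beside the target on chromosome 14, where the gene name table places Enoph1, Hnrnpdl and Hnrnpd near each other. Hnrnpdl had a log2 value of 0.53 with an SE of 0.076. Enoph1 overlaps Hnrnpdl in that table and had a log2 value of -0.46 with an SE of 0.067 (edgeR adjusted p = 0.0576). Neither gene passed over all genes in edgeR, and both values stay unexplained.

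The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 10 genes, and the highest of the others called 71, all in 1 direction. As many genes as in the real split were called in 2 of the 10 splits, and the same number, 2, held for the genes higher (3 against 71), the genes lower (7 against 71) and those with at least a 2-fold change (2 against 5). On FPKM the real split called 0 genes, a count that all 10 splits reach whatever they call, so this comparison tells nothing (highest other 2). Camera with the preset correlation called 7 lists in the real split and 13 in the highest other, and 7 of the 10 splits gave as many. For the median of interferon-stimulated genes the real value was 0.72 and the highest other 0.56, so 1 split of 10 gave as much. For glycolysis and hypoxia it was 2 of 10. At an unadjusted p under 0.05 the real split had 1355 genes and the highest other 2309. The split with 71 and 2309 genes set control 1, control 2 and siHnrnpd 2 against the rest and points to a structure of the samples that the groups do not follow. A partial mitochondrial share of the counts parts the libraries in the same way. It covers the 11 matched of 13 listed mitochondrial protein genes. Mt-cox3 and Mt-cytb, at 0.64% and 0.59% of all counts, are left out because their names did not match the list. The matched genes took 5.22%, 4.67% and 4.88% in control 1, control 2 and siHnrnpd 2, against 3.82%, 3.82% and 3.98% in control 3, siHnrnpd 1 and siHnrnpd 3. Mitochondrial rRNA took 0.42%, 0.43% and 0.37% against 0.33%, 0.20% and 0.23%. The source of this was not tested. On the first principal component, 35.3% of the variance, control 1, control 2 and siHnrnpd 2 lay at 19.7, 16.0 and 1.61. Control 3, siHnrnpd 1 and siHnrnpd 3 lay at -1.20, -11.4 and -24.6. Its sign thus follows that same split, but siHnrnpd 2 at 1.61 and control 3 at -1.20 lay close to each other. The component also follows the groups, with control 1 and control 2 highest and siHnrnpd 1 and siHnrnpd 3 lowest. The siHnrnpd and control groups overlapped on it only through siHnrnpd 2 and control 3. Across genes, the rank correlation of a library's deviation from the mean with gene length ran from -0.30 in siHnrnpd 1 to 0.21 in control 1 and siHnrnpd 3, and genes are not independent replicates.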
